A study of Rattus norvegicus with 12 samples.

How the data were processed

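Poly(A) RNA from rat Schwann cell cultures and from cultures of dissociated adult rat dorsal root ganglia was sequenced from dUTP directional libraries, with 3 control and 3 dichloroacetate libraries per culture type. The treatment was 1 mM dichloroacetate for 24 h. By the labels, the Schwann cells were bought as primary cells and grown in coated flasks, and the ganglion cells came from 3 male rats and filled a plate of 6 wells. The replicates are flasks or wells, and the labels do not say whether the cells of the 3 rats were pooled before plating. The p values therefore measure the spread between cultures, and how much spread between animals this holds is not known. The labels do not pair a treated with a control library, and equal replicate numbers were treated as a block only as an alternative.

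The authors deposited 2 tables, 1 per culture type, and named fastp, HISAT2, featureCounts and DESeq2 as their tools without versions. The raw read counts per gene and library were deposited by the authors as whole numbers. The deposited signal columns hold the authors' size-factor normalized counts, per library and as group means. The deposited fpkm columns hold the authors' FPKM, which scale fragments by transcript length and by the total of the library. The deposited fold changes are log2 ratios of treated over control, made by the authors with DESeq2. The deposited p_value columns hold the authors' p and adjusted p, where a gene without an adjusted p carries a 1. Neither the genome build nor the strand setting of the counting was stated, so coordinates are quoted as the tables give them. The Schwann cell table lists 19046 genes, of which 1283 are unnamed loci from transcript assembly, and the ganglion table lists 21816 genes, of which 1496 are such loci. Symbols that a spreadsheet had turned into dates were found for 24 and 27 genes in the Schwann cell and ganglion table, and these genes were tested under their Ensembl identifiers.

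The raw counts were used for every test. Each library held 17217907 to 22162532 counts. Each table was normalized and fitted alone in R 4.3.3 with edgeR 4.0.16, using the filterByExpr filter, TMM size factors and the robust quasi-likelihood F test, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. After the filter, 13783 genes were tested in Schwann cells and 15575 in ganglion cultures. Levels are CPM, the counts scaled by library total and TMM factor, and errors of log2 fold changes are standard errors from the fit. The difference between the responses of the culture types was tested as an interaction over all 12 libraries for the 15479 genes listed in both tables that passed the filter. Fold changes of both culture types were compared across genes, and overlaps of genes at an unadjusted p under 0.05 were tested with Fisher's exact test, one-sided for more overlap.

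There were 36 gene lists, covering the pyruvate dehydrogenase complex, dichloroacetate metabolism, energy metabolism, lipid synthesis and oxidation, stress responses, inflammation, neurons, glia, matrix, proliferation, ribosomes and markers of other cell types. Lists with at least 5 measured members were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with an estimated correlation as the alternative and fry beside it. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. That rule took the kinases Pdk1 to Pdk4 and Gstz1 in every case, and up to 10 genes per direction with the largest fold changes among genes past the threshold with a symbol, a mean of at least 1 CPM and groups that did not overlap. With fewer than 5 such genes it took the 5 smallest p values per direction. It also took up to 4 members with the smallest p from each list past its test, and from the pyruvate dehydrogenase, glycolysis, sensory neuron, ion channel, myelin and Schwann lineage lists in every case. Protein-coding genes that share their symbol with another listed gene, or are described as like another gene, were counted as near-copy genes.

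The alternatives chosen beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile size factors, no filter and a stricter filter on low counts, a fit over all 12 libraries, mitochondrial genes left out, a replicate block, and each library left out in turn. Fits with the slope of each library's expression on gene length as a covariate, with 1 surrogate variable from sva 3.50.0, and without near-copy genes were chosen after the data had been seen. The length slope of a library is the regression slope of its log2 CPM, taken as the deviation from the mean of all 6 libraries of its culture type, on the log2 length of the gene. Splits of the same libraries into other groups were counted for each test across genes.

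The procedure was tested on simulated data with the means and spreads of these libraries. Each gene was drawn independently, so variation shared between genes was absent except for a simulated length gradient. The shares of unchanged genes among the calls may therefore not hold for the real libraries. In ganglion cultures, edgeR recovered 10% of simulated 2-fold and 87% of simulated 4-fold changes, and in Schwann cells 60% and 90.9%. DESeq2 recovered more 2-fold changes in ganglion cultures, 33%, and 29.2% of its calls there were unchanged genes, against 6.73% for edgeR. With a simulated length gradient, the length slope raised the recovered share of 2-fold changes from 69% to 77%, and the unchanged share of its calls from 0.629% to 9.74%. That simulation took its spreads from the fit with the slope, and its gradient acted through gene length alone. Its shares therefore cannot be set beside the 10%. The interaction test recovered 2% of 2-fold and 66% of 4-fold differences. The authors' own p values were left out of the counts reported here, and FPKM values were used only to check the units. No reads were available, so read quality, strand and duplicate rates were not examined.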

Results

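Gene expression was measured by RNA sequencing in 2 kinds of rat culture: Schwann cells (SC), the glia of peripheral nerves, and dissociated dorsal root ganglia (DRG), which hold the cell bodies of sensory neurons together with their glia. Cultures were left untreated or given 1 mM dichloroacetate (DCA), an inhibitor of the pyruvate dehydrogenase kinases, for 24 h. Each of the 4 groups held 3 libraries. The SC control libraries 1, 3 and 4 held 19034897, 17217907 and 19276149 counts, and SC_DCA libraries 1, 2 and 3 held 19336981, 22162532 and 20141145 counts. The DRG control libraries 1, 2 and 3 held 19097077, 20217956 and 20374948 counts, and the DRG_DCA libraries 1, 2 and 3 held 21169700, 18689709 and 20185685 counts. Levels are given in CPM as mean ± SD over the 3 libraries of a group, and log2 fold changes as treated over control with their SE.

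The first comparison asked which genes of Schwann cells changed with DCA. In Schwann cells, LOC100911730, which is described as like the membrane protein CD151, rose from 18.3 ± 1.71 to 68.9 ± 9.75 CPM (n = 3), and every treated library lay above every control library. Txnip, an inhibitor of glucose uptake whose expression follows glucose supply, lay at 72.7 ± 2.94 CPM in control and 104 ± 12.5 CPM in treated libraries, a difference that did not pass (log2 fold change 0.52, SE 0.126, adjusted p = 1). The drug's targets did not pass either: Pdk3 was at 25.7 ± 2.81 and 20.7 ± 2.34 CPM and Pdk1 at 11.1 ± 1.66 and 13.4 ± 0.674 CPM.

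LOC100911730 (ENSRNOG00000046094, chromosome 1, 214446659 to 214450666, plus strand, build not named) was the only gene of 13783 past the threshold with edgeR, with a log2 fold change of 1.91 (SE 0.154, adjusted p = 0.00661). At an unadjusted p under 0.05 there were 121 genes, 64 higher and 57 lower, and DESeq2 called 8, of which 5 were higher, where other groupings of the same 6 libraries gave it 0 to 419. The groups did not overlap for 699 genes, 5.07% of those tested, where chance gives 10%. The adjusted p of LOC100911730 was 0.0564 without SC_control 3 and 0.0645 without SC_control 4, and in a fit over all 12 libraries edgeR called 0 genes, with 294 at an unadjusted p under 0.05. It lies in a stretch of chromosome 1 that the annotation holds as a pair of copies, and the 7 other measured genes of that stretch varied by a median of 10.4-fold between libraries of a group, against 1.33-fold for LOC100911730.

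Of the other named genes with the smallest p values, none passed (adjusted p = 1 each). The higher ones were Miip, an inhibitor of cell migration, at a log2 fold change of 3.17 (SE 0.666), Tsr2 at 1.43 (SE 0.333), N4bp3 at 3.29 (SE 0.883) and the deacetylase Hdac6 at 0.86 (SE 0.233). Levels in control libraries were low for Miip (0.271 CPM) and N4bp3 (0.196 CPM). The lower ones were Eif3h, a subunit of a translation initiation factor, at -2.19 (SE 0.364), Dusp11 at -3.56 (SE 0.873), Marf1 at -1.30 (SE 0.354), Fam134b at -0.93 (SE 0.282) and Wdr27 at -0.95 (SE 0.332). Hdac6, Eif3h, Dusp11 and Fam134b are near-copy genes, and such genes made up 20% of the 50 genes with the smallest p against 4.26% of all genes tested (Fisher's exact test, p = 4e-05). The counts of both Eif3h copies together differed by a log2 ratio of 0.02 (SE 0.436), and those of both Dusp11 copies by -3.59 (SE 1.03).

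**Figure D1:**
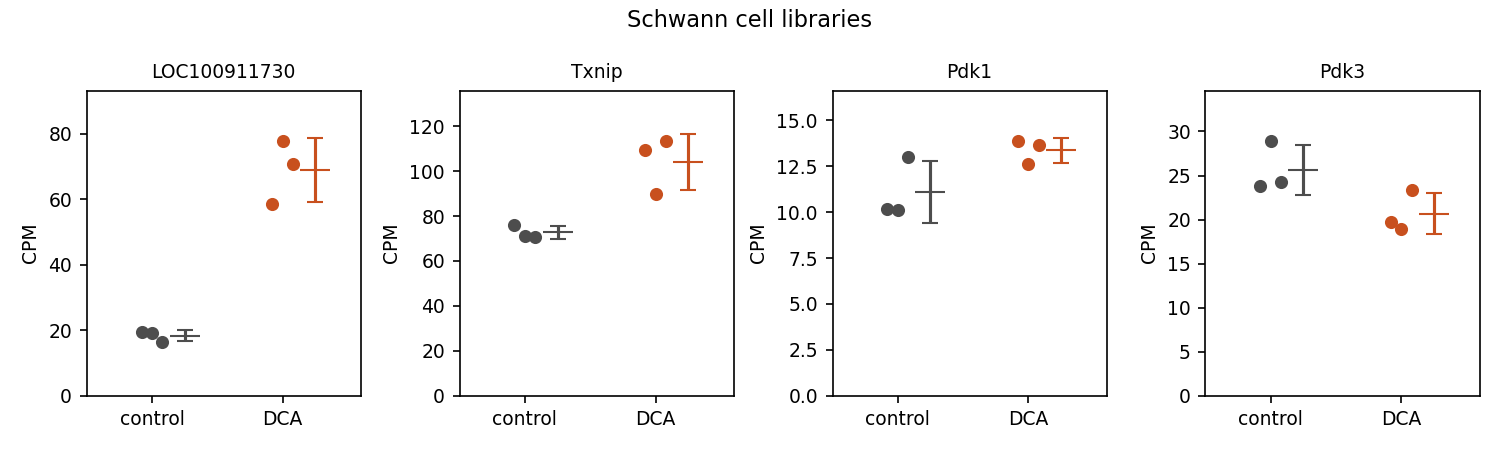
Levels of LOC100911730, Txnip, Pdk1 and Pdk3 in CPM (y axis) in SC control and SC_DCA libraries, where points are libraries and the lines beside them are means ± SD of 3 libraries. LOC100911730 lay at 18.3 CPM in control and 68.9 CPM in treated libraries, while the other 3 genes did not pass the test.

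Among the gene lists, the cell cycle genes of Schwann cells passed as lower, with an adjusted p = 0.0163 at the preset correlation and an adjusted p = 0.848 with an estimated correlation. Of the 27 measured cell cycle genes, 23 lay below 0 and 4 above, with a median log2 fold change of -0.13, but no member passed over all genes or adjusted over the list alone. The examples with the smallest p were the spindle factor Tpx2 at -0.31, the replication helicase subunit Mcm7 at -0.20, the mitotic kinase Aurkb at -0.20 and E2f1, which lay higher at 0.27. The list's adjusted p was 0.642 without SC_control 3, with a median of -0.03, and 0.378 without SC_DCA 2 and 0.16 without SC_DCA 3. SC_control 3 stood apart from the other Schwann cell libraries on their main axis of variation. Its score on that first principal component (41.8% of the variance) was 62.7, against -14.2 to -10.8 for the others.

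The other 31 lists tested in Schwann cells did not pass, and 0 of their members passed, both over all genes and adjusted over the list alone. The lists nearest the threshold were the immediate early genes induced by dissociation (median log2 fold change 0.14, adjusted p = 0.112), the repair Schwann cell genes (0.14, adjusted p = 0.204) and the cholesterol synthesis genes (-0.09, adjusted p = 0.288). Schwann lineage genes had a median of -0.07 (adjusted p = 0.692), with Cryab at -0.30, Sox2 at 0.30, Erbb3 at 0.17 and Gfap at -0.16. Myelin genes had a median of -0.01 (adjusted p = 0.855), with Cmtm5 at -0.20, Pmp22 at -0.17, Pmp2 at -0.30 and Gjb1 at 0.34. Glycolysis genes had a median of 0.04 (adjusted p = 0.441), with Pfkm at 0.23, Pfkl at 0.22, Pfkfb3 at 0.22 and the lactate exporter Slc16a3 at 0.32. The lists of p53 targets and neurotrophic factors shared an adjusted p of 0.417, nerve injury genes were at 0.441, and the TCA cycle, HIF targets, heat shock and fibroblast markers at 0.497. Macrophage markers and the unfolded protein response of the endoplasmic reticulum (ER) were at 0.558, and ion channels at 0.668, with Cacna1c at 0.25, Cacna1h at 0.72 and Scn2a at -0.34. The interferon, synaptic, mitochondrially encoded, satellite glia and ribosomal protein lists shared an adjusted p of 0.692. Fatty acid oxidation genes were at 0.715, and matrix, pericyte and NRF2 target genes at 0.741. Nuclear genes of oxidative phosphorylation, sensory neuron genes and NF-kB targets were at 0.855, the sensory neuron list with Trpm8 at 1.09, Ntrk3 at 0.55, Prph at -0.47 and Piezo2 at -0.28. ATF4 targets were at 0.857 and fatty acid synthesis genes at 0.903. The lists of DCA metabolism and of endothelial, adipocyte and oligodendrocyte markers had fewer than 5 measured members and were not tested.

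The genes of the pyruvate dehydrogenase system, which the drug acts on, were examined in both culture types. This system sets how much pyruvate enters the mitochondria's TCA cycle, and none of its 13 measured genes passed in either culture type, over all genes or adjusted over the list alone. The list had 15 genes, and Pdha1 was among those that matched no listed gene and were not measured. In Schwann cells, log2 fold changes were -0.31 (SE 0.153) for Pdk3, 0.27 (SE 0.172) for Pdk1, -0.18 (SE 0.391) for Pdk4, 0.02 (SE 0.124) for Pdk2, 0.38 for the phosphatase regulator Pdpr and 0.22 for the pyruvate carrier Mpc2. In DRG cultures they were 0.56 (SE 0.352) for Pdk4, 0.11 (SE 0.141) for Pdk3, 0.09 (SE 0.138) for Pdk1, 0.02 (SE 0.128) for Pdk2, -0.41 for Mpc2 and 0.13 for Pdp1. Gstz1, the enzyme that metabolizes DCA, lay at -0.14 (SE 0.196) in Schwann cells and -0.31 (SE 0.247) in DRG cultures. The list's median was 0.00 in Schwann cells (adjusted p = 0.857) and 0.03 in DRG cultures (adjusted p = 0.693).

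The second comparison asked which genes of DRG cultures changed with DCA. The glial filament gene Gfap lay at 31.4 ± 4.38 CPM in control and 12.7 ± 1.52 CPM in treated wells, and the cytokine gene Il11 at 30.4 ± 6.32 and 13.5 ± 1.42 CPM (n = 3). Ephx1, which detoxifies epoxides, lay at 15.4 ± 4.04 and 40.5 ± 6.94 CPM, and the adhesion gene Hepacam at 9.39 ± 0.404 and 20.2 ± 2.46 CPM. The heme oxygenase gene Hmox1 lay at 3209 ± 603 and 5322 ± 786 CPM. For these 5 genes the groups did not overlap, yet none passed in the planned test.

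With edgeR, 0 of 15575 genes passed, 323 had an unadjusted p under 0.05 (157 higher and 166 lower), and DESeq2 called 20, of which 12 were higher, where other groupings of the same 6 libraries gave it 2 to 3125. The groups did not overlap for 1104 genes, 7.09%, where chance gives 10%. The 5 named genes with the smallest p on the higher side were Hepacam at a log2 fold change of 1.10 (SE 0.165), Rasd2 at 1.03 (SE 0.163), the glutamine transporter gene Slc38a3 at 2.86 (SE 0.459), Ephx1 at 1.40 (SE 0.244) and Trim80 at 1.59 (SE 0.282). On the lower side they were Gfap at -1.30 (SE 0.18), Il11 at -1.17 (SE 0.199), the collagen gene Col16a1 at -0.64 (SE 0.114), the Wnt inhibitor Nkd2 at -0.78 (SE 0.147) and Rpl7a at -2.62 (SE 0.519), a near-copy gene whose copies together lay at a log2 ratio of -1.94 (SE 0.562).

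Of 33 lists tested in DRG cultures, 11 passed at the preset correlation, 6 higher and 5 lower, and 0 with an estimated correlation. Schwann lineage genes were lower, with 10 of 12 members below 0, a median log2 fold change of -0.27 and an adjusted p = 1.3e-05 (adjusted p = 0.395 with an estimated correlation). Lower too were nuclear genes of oxidative phosphorylation (-0.29, adjusted p = 0.00039, and 0.728 with an estimated correlation), with Uqcrb at -0.70, Cox7c at -0.66, Atp5g1 at -0.56 and Cox6a1 at -0.51. Ribosomal protein genes had a median of -0.32 (adjusted p = 0.000522, and 0.728 with an estimated correlation), with Rps28 at -0.93, Rps19 at -0.67, Rpl37 at -0.64 and Rps18 at -0.50. Myelin genes had a median of -0.13 (adjusted p = 0.0218, and 0.451 with an estimated correlation), with Cnp at -0.43, Fa2h at -0.30, Mpz at -0.29 and Gjb1 at 0.50. Fibroblast markers had a median of -0.17 (adjusted p = 0.0307, and 0.451 with an estimated correlation), with Igfbp6 at -0.47, Col3a1 at -0.36, Dcn at -0.35 and Fbln1 at -0.26.

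The lists that were higher in treated DRG cultures were stress and defence responses and the mitochondrial genome. Interferon response genes had a median of 0.13 (adjusted p = 0.000977, and 0.678 with an estimated correlation) and NRF2 antioxidant targets 0.09 (adjusted p = 0.00213, and 0.583 with an estimated correlation). HIF targets had a median of 0.15, p53 targets 0.09 and mitochondrially encoded genes 0.18, each with an adjusted p = 0.0061 (adjusted p = 0.451, 0.451 and 0.582 with an estimated correlation). Of the mitochondrial genes, Mt-nd4 lay at 0.50, Mt-nd1 at 0.28, Mt-nd2 at 0.19 and Mt-atp8 at 0.19. ER stress genes had a median of 0.11 (adjusted p = 0.0191, and 0.665 with an estimated correlation). No member passed over all genes. Adjusted over the list alone, 2 p53 targets, 1 immediate early gene and 1 Schwann lineage gene, Gfap, passed. Gfap was also the 1 of 4 genes that passed in the untested list of oligodendrocyte and astrocyte markers. Only the Schwann lineage list passed with each library left out in turn. Without DRG_control 1 the oxidative phosphorylation and ribosomal lists turned higher (medians 0.10 and 0.14), and without DRG_DCA 3 neither passed. The number of lists that passed was 21 without DRG_control 1, 4 without DRG_control 2, 3 without DRG_DCA 1 and 6 without DRG_DCA 2, and without DRG_control 2 the median of the NRF2 targets turned to -0.02.

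The DRG libraries differed along a gradient in gene length, within the control as within the treated group. The regression slope of expression on log2 gene length was -0.218, 0.122 and 0.0184 log2 per doubling of length in control libraries 1, 2 and 3, and -0.0764, 0.00542 and 0.149 in DRG_DCA libraries 1, 2 and 3. The group means were -0.0261 ± 0.174 and 0.0261 ± 0.114 (n = 3, exact two-sided permutation p = 0.7, where 0.1 is the smallest possible). In Schwann cells the slopes lay between -0.0628 and 0.0527, with an exact two-sided permutation p = 0.9. A fit for DRG cultures with this slope as a covariate was chosen after the data had been seen. The fold changes, list values and p values in the next paragraphs come from it, while levels in CPM are given without the slope. Without the slope, the log2 fold changes were 0.91 for Gdf15, 0.53 for Mdm2 and 0.50 for Hsp90b1, and none of these passed.

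**Figure D2:**
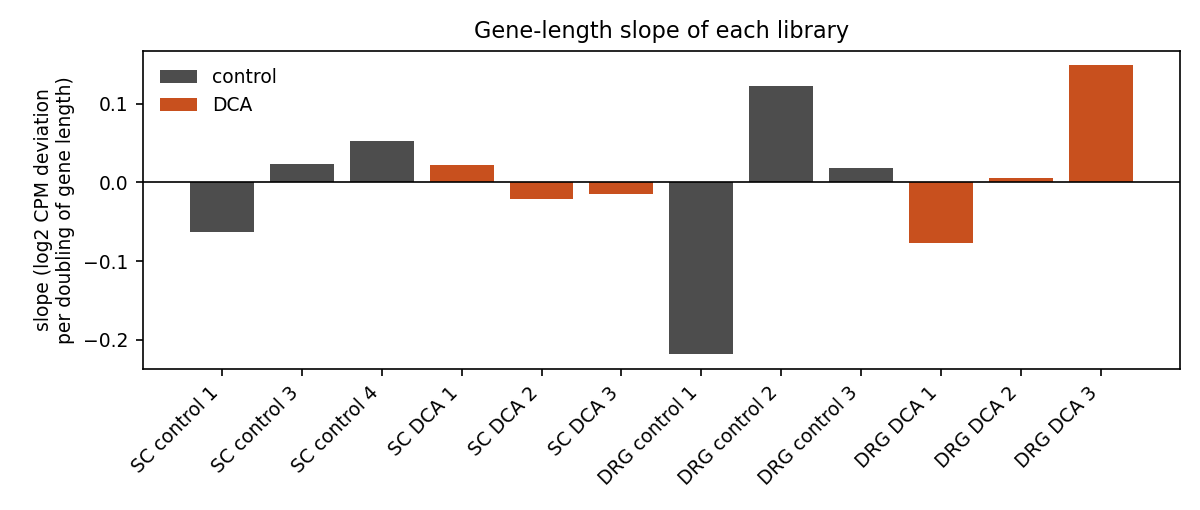
Slope of expression on gene length (log2 CPM per doubling of length, y axis) for each of the 12 libraries, drawn as bars and coloured by group. The DRG control libraries spread from -0.218 to 0.122, the DRG_DCA libraries from -0.0764 to 0.149, and the SC libraries from -0.0628 to 0.0527.

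With the length slope in the fit, single genes of stress responses and of glia passed in DRG cultures, while 0 gene lists passed with an estimated correlation. Hmox1, the main enzyme of heme breakdown, rose (log2 fold change 0.82, SE 0.0524, adjusted p = 3.49e-09), as did Ephx1 (1.52, SE 0.109, adjusted p = 7.89e-09) and the stress cytokine gene Gdf15, from 39.2 ± 13.1 to 73.5 ± 13.2 CPM (1.08, SE 0.0767, adjusted p = 7.89e-09). The p53 inhibitor gene Mdm2 rose from 141 ± 9.83 to 204 ± 11.7 CPM (0.56, adjusted p = 1.13e-06) and the ER chaperone gene Hsp90b1 from 744 ± 155 to 1052 ± 169 CPM (0.60, adjusted p = 1.29e-06). Gfap fell (-1.24, SE 0.107, adjusted p = 1.61e-07), as did Il11 (-1.11, SE 0.129, adjusted p = 4.76e-05). Of 15575 genes, 331 passed, 169 higher and 162 lower, and 26 of them changed by at least 2-fold. In CPM without the slope, the groups did not overlap for 145 of the 331 (43.8%), against 7.09% of all genes tested. The groups overlapped for Hsp90b1 and, among genes named below, for Hspa5, Pdia4, Cxcl10, Ero1l, Kdm3a, Cdkn1a, Cdh19, Cnp, Mpz and Slc2a1, among others.

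The other large rises that passed were Pcgf1 at a log2 fold change of 3.96, Slc38a3 at 2.98, Trim80 at 1.76, the costimulatory receptor gene Cd80 at 1.66, Nwd1 at 1.57, Pamr1 at 1.22, Lypd1 at 1.10 and Hepacam at 1.06, and Rasd2 rose by 0.99. Levels in control libraries were low for Pcgf1 (0.285 CPM), Slc38a3 (0.36 CPM), Cd80 (0.903 CPM) and Nwd1 (0.962 CPM). The other large falls were Dusp11 at -2.24 and Hiat1 at -1.37, both near-copy genes, Adamts14 at -1.15, the growth factor genes Fgf5 at -1.01 and Artn at -0.88, the clock gene Npas2 at -0.87, the chemokine gene Cxcl14 at -0.83 and the collagen gene Col7a1 at -0.77. Col16a1 fell by 0.63 and Nkd2 by 0.74. Of 45 named genes that passed, 22 passed with each library left out in turn and 23 did not. The count of genes fell to 122 without DRG_control 2, 211 without DRG_control 3, 214 without DRG_DCA 2 and 221 without DRG_DCA 1, and was 706 without DRG_DCA 3. Among genes given here, Pcgf1, Cd80, Nwd1, Pamr1, Lypd1, Dusp11, Hiat1, Adamts14, Fgf5, Artn and Npas2 lost the call at least once, all but Nwd1 without DRG_control 2, and Nwd1 without DRG_control 3 and without DRG_DCA 1.

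**Figure D3:**
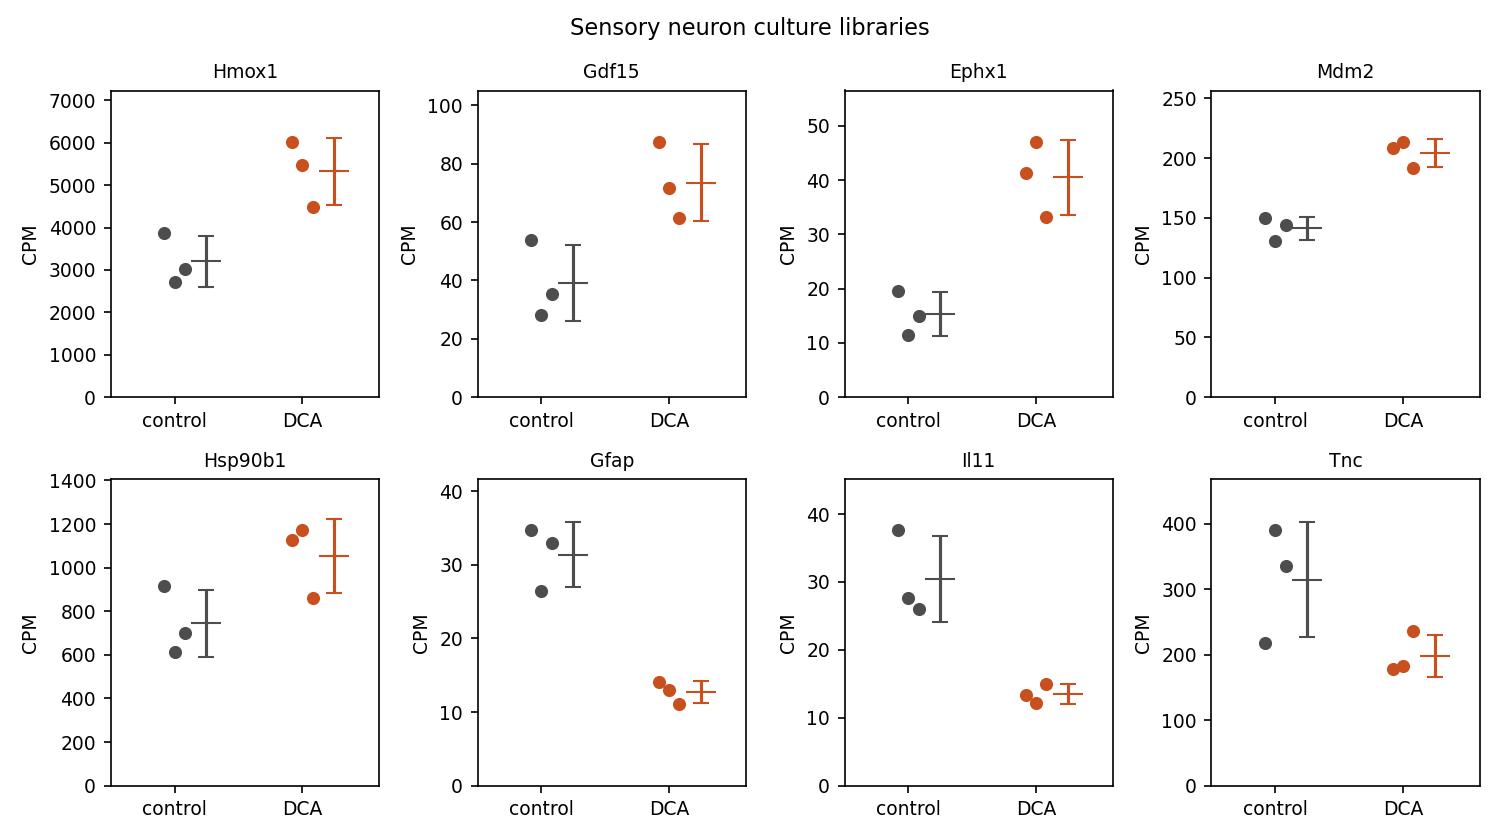
Levels of Hmox1, Gdf15, Ephx1, Mdm2, Hsp90b1, Gfap, Il11 and Tnc in CPM (y axis) in DRG control and DRG_DCA libraries, without the length covariate, where points are libraries and the lines beside them are means ± SD of 3 libraries. Hmox1 lay at 3209 CPM in control and 5322 CPM in treated libraries, and Gfap at 31.4 and 12.7 CPM.

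At the preset correlation, the lists of NRF2, HIF and p53 targets, ER stress genes and interferon response genes were among those higher in this fit, and the smallest adjusted p of any list with an estimated correlation was 0.108. Of 20 NRF2 targets, which defend against oxidants, 8 rose, 0 fell and 12 did not pass, and adjusted over the list alone 11 rose and 2 fell (list adjusted p = 1.21e-17, adjusted p = 0.108 with an estimated correlation). Beside Hmox1 they included Osgin1 at 0.84, the cystine transporter gene Slc7a11 at 0.85 and G6pdx at 0.27. Of 18 ER stress genes, 6 rose and 0 fell, and adjusted over the list alone 8 rose, with Hsp90b1, the chaperone gene Hspa5 at 0.38 and Pdia4 at 0.31 (list adjusted p = 1.37e-09, adjusted p = 0.108 with an estimated correlation). Of 23 interferon response genes, 4 rose and 0 fell, and adjusted over the list alone 10 rose and 1 fell, with Gbp2 at 0.49 and Cxcl10 at 0.84 (list adjusted p = 1.37e-08, adjusted p = 0.256 with an estimated correlation). Of 18 HIF targets, 5 rose and 0 fell, and adjusted over the list alone 7 rose, with P4ha1 at 0.48, the peptide hormone gene Adm at 0.63, Ero1l at 0.32 and Kdm3a at 0.27 (list adjusted p = 2.28e-06, adjusted p = 0.108 with an estimated correlation). Of 16 p53 targets, 4 rose and 0 fell, and adjusted over the list alone 6 rose and 1 fell, with Mdm2, the death receptor gene Fas at 0.95 and the cell cycle inhibitor gene Cdkn1a at 0.38 (list adjusted p = 4.07e-06, adjusted p = 0.108 with an estimated correlation). These 5 lists passed with each library left out in turn, but without DRG_control 2 the single genes Slc7a11, G6pdx, Pdia4, Cxcl10, Adm, Ero1l, Kdm3a, Fas and Cdkn1a did not.

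Of 12 Schwann lineage genes, 6 fell, 1 rose and 5 did not pass, and adjusted over the list alone 6 fell and 2 rose (median -0.27, list adjusted p = 1.37e-08, adjusted p = 0.145 with an estimated correlation). Gfap fell most, with Cdh19 at -0.56, the adhesion gene Cadm4 at -0.47 and the progenitor factor gene Sox2 at -0.39. The small heat shock protein gene Cryab, chosen after its values were seen, was the member that rose, by 0.47. Of 18 myelin genes, 2 fell, Cnp at -0.33 and the main myelin protein gene Mpz at -0.21, and adjusted over the list alone 4 fell and 1 rose (list adjusted p = 0.00617, adjusted p = 0.227 with an estimated correlation). Of 16 repair Schwann cell genes 3 fell and 0 rose, and adjusted over the list alone 4 fell (list adjusted p = 0.00171, adjusted p = 0.278 with an estimated correlation). These 3 lists passed with each library left out in turn, but Cdh19 and Mpz did not pass without DRG_control 2.

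Matrix genes went both ways, with 3 of 27 higher and 4 lower, and adjusted over the list alone 5 in each direction (list median -0.08, adjusted p = 0.0424, adjusted p = 0.256 with an estimated correlation). Chosen after their values were seen, the adhesion modulator gene Tnc fell from 315 ± 88.1 to 199 ± 32 CPM (-0.75, SE 0.0541, adjusted p = 7.89e-09) and fibronectin, Fn1, by 0.55, while the matrix protease gene Mmp2 rose by 0.81. Fibroblast markers were lower as a list (adjusted p = 0.0294, adjusted p = 0.268 with an estimated correlation), with 0 members past the threshold and 3 lower adjusted over the list alone. The matrix list lost its call without DRG_control 2, DRG_control 3 and DRG_DCA 3, with adjusted p up to 0.211, and the fibroblast list without DRG_control 3 and DRG_DCA 3, up to 0.178.

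Few neuronal genes passed, but in each list below the share was no lower than that over all genes, 331 of 15575. Of 30 sensory neuron genes 1 fell, and the list did not pass (median -0.04, adjusted p = 0.065), with Nefm at -0.11, Tubb3 at -0.07, Trpa1 at 0.15 and Elavl4 at -0.18, none of which passed. Of 28 synaptic vesicle and transport genes 1 fell, and adjusted over the list alone 5 fell (list median -0.07, adjusted p = 0.000145, adjusted p = 0.266 with an estimated correlation), and this list passed with each library left out. Of 46 ion channel genes 1 fell (list adjusted p = 0.0183, adjusted p = 0.403 with an estimated correlation), with Kcnk2 at -0.34, Scn11a at 0.12 and Scn1b at -0.09, none of which passed. The median of the ion channels was 0.04 without the length slope and -0.07 with it, and the call was lost without DRG_control 2 and DRG_DCA 2, with adjusted p up to 0.156. Neurotrophic factors (adjusted p = 0.317) and nerve injury genes (0.837) did not pass, with 1 gene lower in the first and 1 higher in the second.

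Few metabolic genes passed either, where 331 of 15575 passed over all genes. Nuclear oxidative phosphorylation genes had a median of -0.04 with 0 of 37 past the threshold (list adjusted p = 0.0166, adjusted p = 0.227 with an estimated correlation, 0.0733 without DRG_DCA 1), and ribosomal proteins a median of -0.03 (adjusted p = 0.0848). The 11 measured mitochondrially encoded genes had a median of 0.17 with 0 past the threshold (list adjusted p = 0.000559, adjusted p = 0.28 with an estimated correlation, 0.0566 without DRG_DCA 2). Mt-co3 and Mt-cyb matched no listed gene and were not among them. Glycolysis genes had a median of 0.07 with 1 of 23 higher, the glucose transporter gene Slc2a1 at 0.21 (list adjusted p = 0.0406, adjusted p = 0.256 with an estimated correlation), against a median of -0.04 without the slope. The other named glycolysis genes, Hk2 at 0.22, Slc16a3 at -0.11 and Eno2 at -1.70, which turned to 0.04 without DRG_control 2, did not pass, and Slc2a1 did not without DRG_control 2. Cholesterol synthesis genes were higher as a list (adjusted p = 0.0144, adjusted p = 0.227 with an estimated correlation, 1 of 25 genes higher) and fatty acid synthesis genes lower (adjusted p = 0.0424, adjusted p = 0.265 with an estimated correlation, 0 of 13 genes past the threshold). The glycolysis list reached an adjusted p of 0.303, the cholesterol list 0.0539 and the fatty acid synthesis list 0.151 with 1 library left out, DRG_control 2 being among those that ended each call. The TCA cycle (adjusted p = 0.928), pyruvate dehydrogenase (0.418) and fatty acid oxidation lists (0.534) did not pass.

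The remaining lists with a call were higher. Heat shock genes had 1 of 10 higher (list adjusted p = 0.000559, adjusted p = 0.268 with an estimated correlation) and passed with each library left out. Immediate early genes had 3 of 16 higher (list adjusted p = 0.0183, adjusted p = 0.256 with an estimated correlation), ATF4 targets 4 of 29 (0.0292, adjusted p = 0.256 with an estimated correlation), cell cycle genes 1 of 26 (0.0189, adjusted p = 0.227 with an estimated correlation) and macrophage markers 1 of 15 (0.0454, adjusted p = 0.256 with an estimated correlation). Each of these 4 lost its call with at least 1 library left out, among them DRG_control 2 in every case, with adjusted p up to 0.192. NF-kB targets (adjusted p = 0.0563), satellite glia (0.174), pericyte (0.507) and endothelial markers (0.881) did not pass. The lists of DCA metabolism, adipocyte and oligodendrocyte markers were too short to test.

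**Figure D4:**
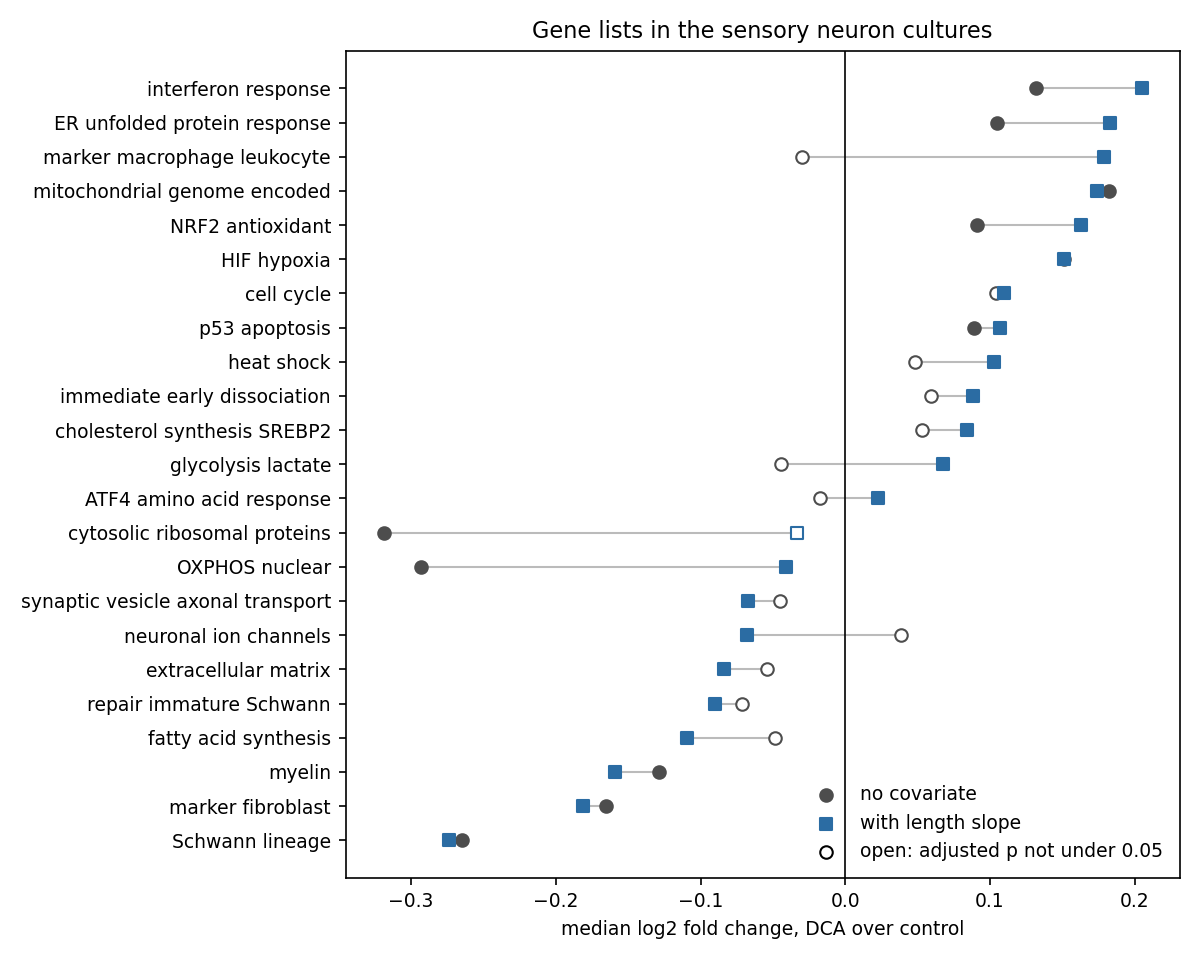
Median log2 fold change in DRG cultures of each gene list that passed in at least 1 of the fits (x axis, treated over control), without and with the length slope in the fit, where open symbols mark lists with an adjusted p of 0.05 or more. The medians of oxidative phosphorylation and ribosomal protein genes moved from -0.29 and -0.32 to -0.04 and -0.03, while that of Schwann lineage genes stayed at -0.27.

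The third comparison asked whether Schwann cells and DRG cultures responded differently to DCA. The log2 fold change of Gfap was -0.16 in Schwann cells and -1.30 in DRG cultures, a difference of 1.15 (SE 0.213) that did not pass (adjusted p = 1). That of Ephx1 differed by -1.31 (SE 0.287, adjusted p = 1), with the larger value in DRG cultures. The other named genes with the smallest p were Nkd2 (0.85, SE 0.18), Fgf5 (1.31), Kcnk12 (3.35), Rgs20 (4.54), Tmem55a (-0.64), Cadm3 (-1.75), Trim80 (-2.28) and Mmp2 (-0.78), and none passed. Kcnk12, Rgs20 and Trim80 had too few counts in Schwann cells to be tested there, and the DRG log2 fold changes of Kcnk12 and Rgs20 were -0.08 and -0.09. The differences were -0.41 for Pdk3, -0.74 for Pdk4, 0.18 for Pdk1, 0.18 for Gstz1 and 0.00 for Pdk2, none past the threshold. With edgeR, 0 of 15479 genes passed, 450 had an unadjusted p under 0.05, and DESeq2 called 7, of which 3 were higher in Schwann cells. With the length slopes of both culture types in the fit, 0 genes passed and 1143 had an unadjusted p under 0.05.

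The log2 fold changes of both culture types were compared across the 13096 genes tested in both, which are not independent replicates. Pearson's r was -0.0256 and Spearman's rho -0.0703. At an unadjusted p under 0.05, 59 genes were higher in Schwann cells and 118 in DRG cultures, and 1 unnamed locus was higher in both, where independence gives 0.532 (Fisher's exact test, one-sided, p = 0.414). On the lower side there were 43 and 129 genes, and the near-copy gene Dusp11 was lower in both, where independence gives 0.424 (Fisher's exact test, one-sided, p = 0.347). The sign of r turned without SC_control 4 (0.057) and without DRG_DCA 2 (0.0527), and r was -0.139 without SC_control 1, -0.117 without DRG_DCA 3 and -0.0936 without DRG_control 1. With the length slopes in the fits, r was -0.0898 and rho -0.196. At the same unadjusted p, 4 genes were then higher in both, where independence gives 6.78, and 1 lower, where it gives 3.05.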

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

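The fits with the length slope or a surrogate variable, those without near-copy genes and every alternative of the length-slope fit were chosen only after the results had been seen. In Schwann cells, where 1 gene passed, DESeq2 called 8, no filter on low counts gave 2, the fit over all 12 libraries 0, the replicate block 6, 1 surrogate variable 2 and leaving out near-copy genes 0, and with single libraries left out the count ran from 0 to 4. In that block only the libraries numbered 1 and 3 had a partner, so SC_control 4 and SC_DCA 2 did not contribute to the fold changes. The count of 1 list became 0 with an estimated correlation, without or with the length slope, and 0 to 4 with single libraries left out. In DRG cultures, where 0 genes passed, DESeq2 called 20, the fit over all 12 libraries 1, the length slope 331 and 1 surrogate variable 384, while each library left out in turn gave 0. The 331 genes became 213 with the replicate block, 1380 with the slope centred within each group, and 122 to 706 with single libraries left out. Of the 331, DESeq2 with the slope shared 287, the surrogate variable 316 and the replicate block 172. The 11 DRG lists became 0 with an estimated correlation, 22 with the length slope, 0 with both, and 3 to 21 with single libraries left out, and the 22 became 0 with an estimated correlation and 13 to 23. With single libraries left out, the median of the oxidative phosphorylation list ran from -0.535 (without DRG_control 2) to 0.102 and that of the ribosomal list from -0.569 (without DRG_control 2) to 0.142, both turning without DRG_control 1, and the ribosomal list's test turned at a median of -0.106 without DRG_DCA 3. The glycolysis list turned to 0.0676 with the length slope, and the ion channels, at up to 0.344 without DRG_control 2, to -0.174 without DRG_control 1, -0.155 without DRG_DCA 3 and -0.0677 with the length slope. For the interaction DESeq2 called 7 genes where edgeR called 0. With the SC and DRG fold changes compared across genes, the correlation of -0.0256 became -0.172 for genes above the median level, 0.0944 for genes that passed in DRG cultures with the slope, and -0.139 to 0.057 with single libraries left out. For single named genes, 363 of 369 values under the alternatives kept their side of the threshold in Schwann cells, 709 of 765 in DRG cultures and 663 of 765 with the length slope, and for single lists 64 of 70 in Schwann cells and 167 of 250 in DRG cultures. Among these, the sign of genes that did not pass turned in 5, 8 and 3 cases, and the test's direction of lists that did not pass in 8 and 15. Leaving out near-copy genes removed the only gene that passed in Schwann cells. For the others the cause was not tested. With 1 gene past the threshold, the comparison of fold changes over genes that passed could not be run, and the pseudocount alternatives did not apply to counts. At these depths and spreads, and with genes drawn independently, simulated 2-fold changes in DRG cultures were recovered in 10% of genes. Where a length gradient was simulated, with the spreads left after the slope was fitted, the shares were 69% without and 77% with the slope. Those 2 shares cannot be set beside the 10%, because the spreads differ.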

Other observations

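Among the tests in this part, those on the duplicated segment, on the gene-length gradient as a source of list changes, on the ion channel genes along it, on the fold changes with the covariate and on the mean response of both culture types, and the splits of the fits with a length slope, were chosen only after the results had been seen. The control libraries show how far the cultures differed before treatment. Of sensory neuron genes, 19 of 20 were higher in DRG cultures, with a median log2 ratio of Schwann cells over DRG of -7.34; peripherin, Prph, a filament of small sensory neurons, lay at 3980 ± 1350 CPM in DRG and 0.913 ± 0.381 CPM in Schwann cell controls. Ion channel genes were higher in DRG cultures in 31 of 35 cases (median -5.03). Of cell cycle genes, 25 of 27 were higher in Schwann cells (median 4.40), with the proliferation marker Mki67 at 256 ± 30.4 CPM against 2.06 ± 0.979 CPM and Top2a at 257 ± 32.9 against 2.40 ± 0.772 CPM.

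Glial and matrix genes were present in both cultures. Of 12 Schwann lineage genes, 11 were higher in Schwann cells and 1 in DRG cultures (median 1.37), with Cadm4 at 2690 ± 192 against 200 ± 18.4 CPM, S100b at 1760 ± 293 against 564 ± 151 CPM and Gfap at 383 ± 49.8 against 30.9 ± 4.16 CPM. Matrix genes were higher in Schwann cells in 23 of 27 cases and in DRG in 3 (median 3.10), and fibroblast markers in 6 and 3 of 9 (median 1.90). Myelin genes split, with 5 of 17 higher in Schwann cells and 10 in DRG (median -0.67). Macrophage markers (8 of 10 genes, median -3.45) and endothelial markers (6 of 6, median -3.37) were higher in DRG cultures, while pericyte markers had 3 of 8 on each side (median -0.78) and satellite glia markers 2 and 3 of 7 (median -0.44). In all, 8907 of 15479 genes differed, 4180 of them higher in Schwann cells. With the 6 control libraries alone 7357 genes differed and the highest of the other splits gave 0, the real split being the 1 of 10 with a count that large, too few splits for a share under 0.05.

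With the length slopes in the fit, the mean response of both culture types passed for 2 of 15479 genes, Gfap at -0.70 (SE 0.0831) and Ephx1 at 0.80 (SE 0.0979), each with an adjusted p = 0.0332. In that fit of each culture type alone, the log2 fold changes were -1.24 and 1.52 in DRG cultures and -0.16 and 0.07 in Schwann cells, so the mean rests on the DRG cultures. Without the slopes edgeR called 0 genes, with 385 at an unadjusted p under 0.05. Of 100 splits, 11 gave at least 2 genes and the highest other gave 234, so chance is not excluded. For the difference between the responses the real count was 0, which all 100 splits must reach, so they test nothing there; 1 split gave 2582 genes and the others 0 to 2, and what set that split apart was not tested. For the remaining counts, 10 splits are too few for a share under 0.05. In Schwann cells, 6 of 10 splits gave at least the real 1 gene, the highest other 5, and 8 of 10 at least the real 1 list, the highest other 6. In DRG cultures, 10 of 10 gave at least the real 0 genes, as any count must, the highest other 1, and 2 of 10 at least the real 11 lists, the highest other 15, from the split of DRG_control 1, DRG_DCA 1 and DRG_DCA 2 against the rest, which follows the length gradient. With the length slope, 1 of 10 splits, the real one, gave as many as 331 genes and 22 lists, the highest others giving 104 and 18. DESeq2 called 8 genes in Schwann cells for the real split and up to 419 for another, and 20 and up to 3125 in DRG cultures, the last for the split that follows the length gradient. Txnip, which did not pass in Schwann cells (adjusted p = 1), rose in DRG cultures with the length slope (log2 fold change 0.30, SE 0.0509, adjusted p = 0.00113), and was chosen there after its values were seen.

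LOC100911730 rose in Schwann cells and belongs to a segment of chromosome 1 with copies at 213951759 to 214074663 and 214389255 to 214511529. Reads moved from its namesake Cd151 in the other copy would leave the sum unchanged, but the counts of both together rose by a log2 fold change of 1.64 (SE 0.331), which argues against that source. The 7 other genes of the segment differed between libraries of a group by a median of 10.4-fold at the widest, against 1.24-fold for the 9 genes between the copies, while LOC100911730 itself differed by 1.33-fold. Unstable assignment of reads between the copies and a rise of the gene cannot be told apart, because its own counts were steady within groups in a segment where most were not.

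Without the length slope, oxidative phosphorylation and ribosomal protein genes passed as lower in treated DRG libraries at the preset correlation of camera only. With an estimated correlation neither list passed (camera, adjusted p = 0.728 each), and 0 members passed over all genes. The gene-length gradient may account for the lower medians, since 87.7% of the median log2 fold change of both lists was lost with the slope in the fit (-0.30 to -0.04). Across 15575 genes, Spearman's rho between the gradient and gene length was 0.512. A positive relation was fixed in advance, because the slope of each library was itself computed from gene length, so it shows nothing about the source. Length explained only 17.4% of the gradient's variance across genes. The slope also followed the main axis of variation between the DRG libraries (first principal component, 59.1% of the variance, rounded Pearson's r of 1). The covariate therefore removed that axis and not only an effect of length. These lists lay further along the gradient than their length predicts, by -2.30 and -2.54 log2 per unit of slope, where 2.5% of random lists lay below -1.10. A different share of neurons in each well would move neuronal genes off that trend together, but the median residual of the sensory neuron genes, -0.633, lay inside the middle 95% of random lists, -1.16 to 0.325, and that of the ion channel genes, 0.637, above theirs, -1.07 to 0.137. The sensory neuron genes alone met what was predicted without a neuron share, but the ion channel genes, examined afterwards, lay off the trend. The neuron share and a technical source of the gradient, such as RNA quality, therefore cannot be told apart, because the neuronal lists differ and no measure of either is given.

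Lower Schwann lineage genes in treated DRG cultures kept 103% of their median of -0.27 with the length slope in the fit, which argues against the gene-length gradient as their cause. A lower share of Schwann cells in the treated wells would lower all members alike only if Schwann cells were their only source. The fold changes of the members differed by more than their errors, with Gfap at -1.24 and Cryab at 0.47 with the length slope. Cochran's Q was 59.8 over 12 genes (p = 1.01e-08 by the chi-squared distribution), and 338 with the length slope. Gfra3, however, lay at 123 ± 8.33 CPM in DRG and 3.5 ± 0.303 CPM in Schwann cell controls, so members can have other sources. The spread therefore cannot decide about a lower share of Schwann cells, which stays open. Of the 331 genes that passed with the covariate, 99.7% had the same sign without it, with a median ratio of 1.07. Their standard errors fell to 0.393 of their size. These genes were chosen by that fit, and the mean slopes of the groups lay close together (-0.0261 and 0.0261). A turned sign was therefore unlikely from the start, and the share cannot exclude changes made by the covariate. Whether the smaller errors gave too many calls is not decided by it. A response of Schwann cells to DCA within the mixed culture is one hypothesis that was not tested, and the Schwann cell cultures did not show it for Gfap (log2 fold change -0.16, SE 0.136). The list cannot assign the change to Schwann cells either, since Cdh19 is also among the satellite glia markers.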
